A study of Homo sapiens with 6 samples.

How the data were processed

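The series measured RNA of human Treg cells on Illumina HT-12 BeadChips, 6 arrays in all. Per the labels' protocols, total RNA was extracted with Trizol, cleaned on columns with DNase treatment, amplified to biotin-labelled cRNA and hybridised. The titles placed 2 arrays in each of 3 groups: 0 h, M at 24 h and G at 24 h. The treatment tags separate only 0 h from 24 h.

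The first deposited table held log2 probe intensities of 47318 probes that were not normalized between arrays, read from the values, since the scanner software and any background step are not given in the sources used here. Its medians in linear intensity lay between 108.8 and 110.5, and the upper quartiles between 208.2 and 223.8. The second deposited table, the values of the series matrix, held log2 intensities that the authors had quantile normalized, again read from the values: the sorted columns differed by at most 0.0218 outside the 10 lowest probes. Its rank order within each array equalled that of the first table (lowest rank correlation 1), its dimmer probes were lower by 24.8 to 26.0 intensity units, and its lowest value was a floor at 0. Its column medians were 6.39 or 6.40. The direction of both scales was that of brightness. Quantile normalization forces equal distributions on all arrays, so a shift of most transcripts between conditions cannot be seen.

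The design written before the data were examined used detection p-values and the neqc method. The tables used here held neither detection p-values nor control probes, so the fallback written in that design was used. The log2 values were turned back to intensities, background corrected with normexp (offset 50), quantile normalized and put on the log2 scale with limma 3.58.1 in R 4.3.3. The 23659 brightest probes by mean over all arrays, 50%, were kept, which set a limit of 6.81. Of the 47318 probes, 30111 had 1 gene symbol, 8 had several and 17199 had none in the table used here. Gene numbers of 30072 probes were found in the GRCh38.p14 gene table, which changed no symbol, and 39 were not found. No coordinates are given, because no build is named for the arrays. Each symbol was represented by its probe of highest mean, and probes without a symbol stayed as features of their own, giving 19454 features, 12243 of them with a symbol. Where other kept probes of a named gene existed, none had the opposite sign at an unadjusted p under 0.05.

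All 6 arrays entered 1 limma fit with a mean per group, since 2 arrays per group are too few to estimate the spread alone. As planned, this fit had no block (3 residual degrees of freedom), so it leaves the pairing by preparation out of account. Contrasts were G minus M at 24 h, the mean of both arms minus 0 h, and each arm minus 0 h. P-values were adjusted by the method of Benjamini and Hochberg, with a threshold of 0.05. A total of 31 gene lists, fixed at the same stage, covered glucose metabolism and its regulators, Treg identity, Toll-like receptor and NF-kB signalling, stress, proliferation and other cell types. They were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists. The preset treats genes of a list as nearly independent, and camera with the correlation estimated per list is given beside each call. These versions differ in more than the correlation. For oxidative phosphorylation at 24 h against 0 h the estimate, -0.01, lay below the preset. Camera's unadjusted p still rose from 1.6e-05 to 0.013. A call lost with an estimated correlation is therefore not by itself a sign of correlated genes. Fry, which asks whether a list's genes move one way on balance, was run in addition.

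The text names, per comparison, up to 8 largest rises and 8 largest falls past the threshold whose groups do not overlap. Where fewer than 5 passed in a direction, it names the 5 of smallest unadjusted p as values that did not pass. It adds up to 4 members of smallest p from lists and a set of genes of Treg identity and glucose use, fixed together with the lists. Sex-linked marker genes, HLA genes, genes with common deletions, receptor segments and unnamed probes were not named. Genes outside this rule were chosen after their values were seen, whether or not marked so, among them the members named because they passed over a list alone or in the fit with the block.

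The titles call the cells Treg-1 and Treg-2 in each condition, which is the basis for treating equal numbers as the same preparation. Deviations from the group means of arrays with the same number correlated, across features, at 0.748 between 0 h and M, 0.72 between 0 h and G and 0.789 between M and G. The first principal component held 68.7% of the variance and separated the numbers. A fit with the number as a block (2 residual degrees of freedom) is therefore given where it changes a call. Errors are large in the fit without the block because they include the difference between preparations. A gene that did not pass in that fit may still differ within both preparations.

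Both fits were tested on simulated data of 19454 features for G minus M, in 20 simulations with 200 changed features each. Without the block 13% of changes of 1 and 85% of changes of 2 on the log2 scale were recovered with 0 false calls. With the block 100% of both sizes were recovered, with a mean of 16.2 false calls, 7.5% of its calls. A list shifted by 0.35 was found in 20 of 20 simulations in either fit. The simulated genes varied independently of each other, so this does not show how the list test behaves with correlated genes. For the list shifted, the glycolytic enzymes, the estimated correlation in the data was 0.49, and 0.65 with the block.

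Alternatives were no background correction, cyclic loess, median scaling, the series matrix values, no filter, every probe as a feature, eBayes with trend and robust, array weights, only the arrays compared, the block, fry, an estimated correlation and each array left out. Normexp with offset 50, listed as an alternative, was the setting used. A filter on detection p and a block for the slide were not used here. Offset 16, the brightest 30% of probes and the combinations of the block with fry, an estimated correlation or left-out arrays were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.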

Results

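Gene expression was measured in human naturally occurring regulatory T cells (Treg), the CD4 T cells that restrain immune responses, isolated from blood mononuclear cells of healthy donors. The 6 Illumina HT-12 BeadChips covered 3 conditions with 2 arrays each: untreated cells at 0 h, and cells at 24 h in arms lettered M and G. Poly-G3, the guanosine oligonucleotide of the study, was used to stimulate TLR8, an endosomal receptor for RNA. The letters M and G are not explained by the labels, and all 4 arrays at 24 h carry the Poly-G3 treatment tag although the design speaks of cells with or without it, so directions are given by letter only. The titles number the Treg preparations 1 and 2, with 1 array of each preparation per condition. Each array held 47318 probes, and the upper quartile of the intensities lay between 208.2 and 223.8, lowest at 0 h and highest in arm G. Precision is limited by the 2 arrays per condition. The labels do not say whether the preparations are separate donors or cultures, so the spread between them may not be that between people. Values are log2 intensities, and errors are standard errors of the limma fit with n = 2 per condition unless stated. That fit has no preparation block, so its errors include the difference between preparations.

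The first comparison, G minus M at 24 h, asked how the arms differed after the same time in culture. Glycolytic enzymes and genes of the hypoxia response were lower in arm G as lists. The 20 measured glycolytic enzymes had a median log2 difference of -0.35 (1.28-fold lower), and 15 of them were lower in both preparations. Chance would give 25% of genes if the preparations were independent. Their G minus M differences correlated at 0.35 over all features, so 25% is too low a reference. Aldolase A (ALDOA) differed by -0.74 ± 0.29 (its dimmer kept probes by -0.09 and -0.48) and hexokinase 2 (HK2) by -0.70 ± 0.40 (its dimmer kept probe by -0.28). The platelet-type phosphofructokinase PFKP differed by -0.43 ± 0.25 (its dimmer kept probe by 0.18), and PFKFB4, which sets fructose-2,6-bisphosphate, by -1.52 ± 0.86. The 20 genes of the HIF-1 and hypoxia list had a median of -0.40 (1.32-fold lower), with 16 lower in both preparations. Among them the vasoactive peptide gene adrenomedullin (ADM) differed by -2.51 ± 1.18, ANKRD37 by -1.18 ± 0.48, the collagen prolyl hydroxylase P4HA1 by -0.93 ± 0.42 and the oxygen sensor EGLN1 by -0.64 ± 0.28. Camera called both lists, the glycolytic enzymes at adjusted p = 0.00099 and the hypoxia list at adjusted p = 7.5e-05. For both lists limma's camera gave adjusted p = 0.86 with an estimated correlation.

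No single gene of these lists passed, whether adjusted over all genes tested or adjusted over the list alone. With the preparation as a block, 7 hypoxia genes were lower when adjusted over the list alone (ADM, ANKRD37, BNIP3, EGLN1, KDM4B, P4HA1 and P4HA2), as was 1 glycolytic enzyme, ALDOA. The call on the glycolytic enzymes was lost without M24h replicate 1 (camera adjusted p = 0.13) and without G24h replicate 2 (adjusted p = 0.2). The hypoxia list lost its call without the same arrays once the preparation was a block (adjusted p = 0.057 and 0.084). Over all alternatives the adjusted p ran from 8.9e-15 to 1 for the glycolytic enzymes and from 4.3e-23 to 1 for the hypoxia list.

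The 7 measured glucose and lactate transporter genes had a median of -0.11 and 5 were lower in both preparations, but camera did not call the list (adjusted p = 0.19), with SLC2A3 (GLUT3) at -0.61 ± 0.34 and SLC2A1 (GLUT1) at -0.51 ± 0.34. The SLC2A3 probe may share sequence with the near-identical SLC2A14. Within the glycolytic list, lactate dehydrogenase A (LDHA) differed by -0.16 ± 0.22, pyruvate kinase PKM by -0.28 ± 0.27 and PFKFB3 by -0.62 ± 0.68, none past the test as single genes. The transcript of the hypoxia factor itself, HIF1A, was at 0.27 ± 0.14 and MTOR at 0.26 ± 0.15, opposite in sign to the hypoxia targets. MYC was at 0.02 ± 0.54, with its dimmer kept probe at 0.32. LDHA turned to 0.06 without G24h replicate 2, and MYC to -0.48 and -0.45 without G24h replicate 1 and M24h replicate 2. The 25 genes of mTORC1 components and regulators had a median of -0.04 (camera adjusted p = 0.94), where camera's own direction was upward.

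Genes of cell division and ribosome production were higher in arm G. The 38 proliferation genes had a median log2 difference of 0.35 (1.28-fold), and 35 were higher in both preparations. The replication clamp PCNA differed by 0.72 ± 0.38 (its dimmer kept probe by 0.00), thymidylate synthase (TYMS) by 0.55 ± 0.40, cyclin E1 (CCNE1) by 0.53 ± 0.31 (its dimmer kept probe by -0.10) and the helicase subunit MCM3 by 0.41 ± 0.31. The 24 ribosome biogenesis genes had a median of 0.20, with 18 higher in both preparations, among them RRS1 at 0.77 ± 0.36 and NOLC1 at 0.60 ± 0.40. The 17 heat shock genes had a median of 0.17, with 10 higher in both preparations, HSPA4 at 0.36 ± 0.18 and HSPA1B, whose sequence is nearly that of HSPA1A, at 0.31 ± 0.13.

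Camera called these 3 lists at adjusted p = 7.5e-05, 0.00033 and 0.022 in that order, and each had adjusted p = 0.86 with an estimated correlation. Estimated without the block, the correlation includes the difference between preparations. It was 0.95, 0.67 and 0.18 in that order, and 0.15, 0.04 and 0.01 with the block. In the blocked fit camera still gave each list adjusted p = 0.57 with an estimated correlation. In the fit with the preparation as a block, 22 proliferation genes and 4 ribosome biogenesis genes (BOP1, DDX21, NOLC1 and RRS1) were higher when adjusted over the list alone, none when adjusted over all genes tested. The calls on all 3 lists were lost without G24h replicate 1 (adjusted p = 0.98 for proliferation, 0.49 for ribosome biogenesis and 0.32 for heat shock) and without M24h replicate 2 (adjusted p = 0.56, 0.66 and 0.5), with the direction of the proliferation list reversed. Once the preparation was a block, the 3 lists kept their calls without any 1 of the 6 arrays. Over all alternatives the adjusted p ran up to 1 from 4.3e-23 for proliferation, 6e-08 for ribosome biogenesis and 0.0041 for heat shock.

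**Figure D1:**
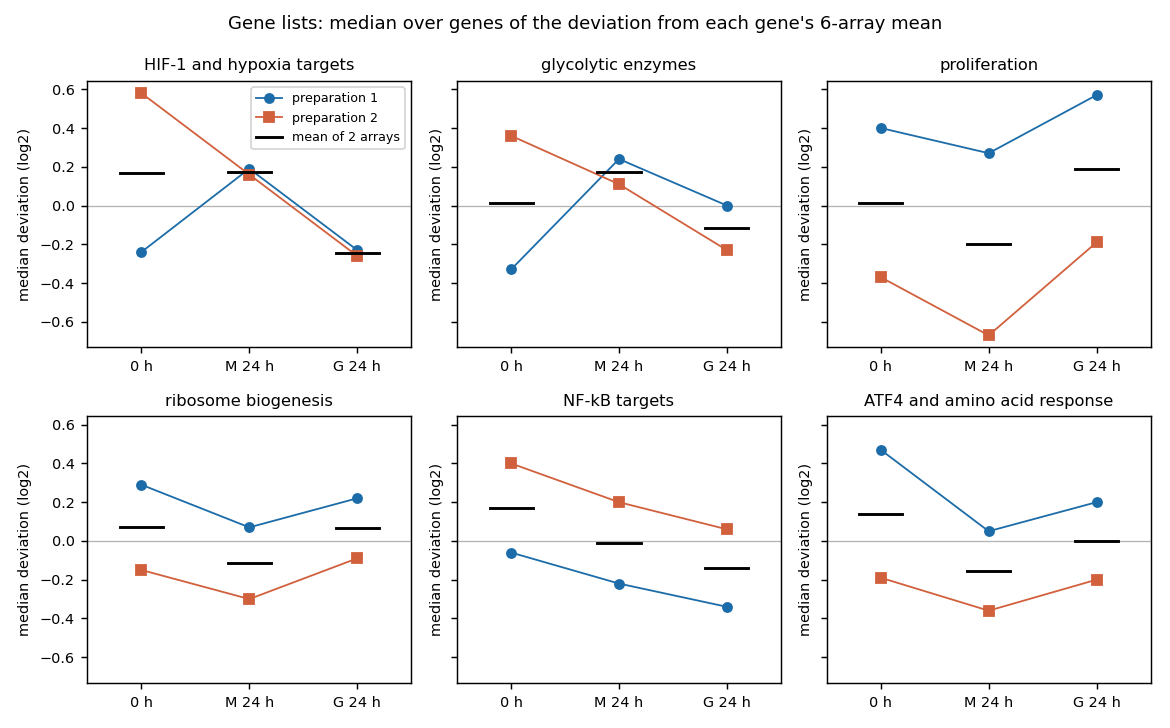
Each panel plots 1 gene list: the y axis is the median over its genes of the log2 deviation from the gene's mean over the 6 arrays, and the x axis gives the condition. Circles and squares are the arrays of preparations 1 and 2, joined by lines, and black bars are the means of 2 arrays. The hypoxia list stood at 0.19 and 0.16 on the M arrays and at -0.23 and -0.26 on the G arrays, while the 2 arrays at 0 h stood apart at -0.24 and 0.58.

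Of the 26 other lists, camera without the block called none, with medians from -0.24 (platelet and erythroid markers) to 0.19 (metallothioneins). The 30 Treg signature genes had a median of -0.04 (camera adjusted p = 0.94). Treg identity genes were among them, with the lineage factor FOXP3 at -0.11 ± 0.17, the IL-2 receptor chain IL2RA at -0.11 ± 0.22, the checkpoint receptor CTLA4 at 0.07 ± 0.71 and IKZF2 at -0.10 ± 0.15. The interleukin subunit EBI3 was at -0.39 ± 0.16. Leaving out single arrays turned the sign of FOXP3 (0.06 without M24h replicate 1 and 0.01 without G24h replicate 1), IL2RA (0.15 without G24h replicate 1 and 0.03 without M24h replicate 2), IKZF2 (0.04 without G24h replicate 1) and CTLA4 (-0.55 without M24h replicate 1 and -0.67 without G24h replicate 2). The 24 Toll-like receptors and adaptors had a median of 0.00 and the 26 NF-kB targets of -0.04, with the adaptor MYD88 at 0.00 ± 0.26, the kinase CHUK at 0.65 ± 0.27 and the NF-kB inhibitor TNFAIP3 at -0.71 ± 0.49. MYD88 was positive under cyclic loess and median scaling, without M24h replicate 1 (0.26) and without G24h replicate 2 (0.24). All 3 TLR8 probes lay below the brightness limit of 6.81, with means from 5.89 to 6.75, so TLR8 was not tested.

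Markers of other cell types did not separate the arms. The medians were -0.09 for 9 monocyte markers (camera's own direction was upward), -0.07 for 5 B cell markers, -0.09 for 7 NK and CD8 T cell markers and 0.14 for 7 dendritic cell markers. The 21 T cell receptor complex and lineage genes had a median of -0.16 (camera adjusted p = 0.058), with CD5 at -0.31 ± 0.13 and the kinase ZAP70 at -0.28 ± 0.14 (its dimmer kept probes at 0.03 and 0.23). With the preparation as a block camera called this list lower (adjusted p = 0.0012) and the ATF4 and amino acid response list, median 0.13, higher (adjusted p = 0.0019). Both had adjusted p = 0.57 with an estimated correlation in that fit. In the ATF4 list CEBPG was at 0.55 ± 0.26 and VLDLR at -0.75 ± 0.47. Fry in the blocked fit called oxidative phosphorylation (median 0.04, adjusted p = 0.043) and no other list. For that list the fit without the block gave adjusted p = 0.19 by camera and 0.52 by fry. When adjusted over the list alone in the blocked fit, RRAGD, CHUK, TNFAIP3, H6PD, RPIA, ACAT2, IDI1, IFNG, CEBPG, PSAT1 and VLDLR also passed, none of them when adjusted over all genes tested. The remaining lists, none of them called by camera in either fit, were the TCA cycle, the pentose phosphate pathway, fatty acid oxidation, cholesterol and fatty acid synthesis, interferon-stimulated genes, p53 targets, the unfolded protein response, immediate early genes, effector cytokines, autophagy, oxidative stress and cytosolic ribosomal proteins.

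Across the 19454 features, limma called 0 for G minus M, with 373 at an unadjusted p under 0.05 where chance gives 973. With the preparation as a block the count was also 0, with 2360 at an unadjusted p under 0.05 and a smallest adjusted p of 0.122. The named genes of smallest p that were higher in arm G, none of them past the test, were the centromere protein CENPW at 0.76 ± 0.18, TIGAR, a fructose-2,6-bisphosphatase, at 0.91 ± 0.23, SNAPC5 at 0.56 ± 0.14, the complex I assembly factor NDUFAF1 at 0.48 ± 0.12 and the kinase PLK3 at 0.52 ± 0.13. Those lower were phospholipase PLCD1 at -0.63 ± 0.13, the inhibitory receptor CD300A at -0.65 ± 0.15, the small nucleolar RNA SNORD13 at -0.78 ± 0.19, CARD14 at -0.52 ± 0.13 and DENND6B at -0.50 ± 0.12. The quinone reductase NQO1 stood at 0.45 ± 0.14. In simulated data with this fit, 13% of genes changed by 1 on the log2 scale were recovered and 85% of those changed by 2.

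**Figure D2:**
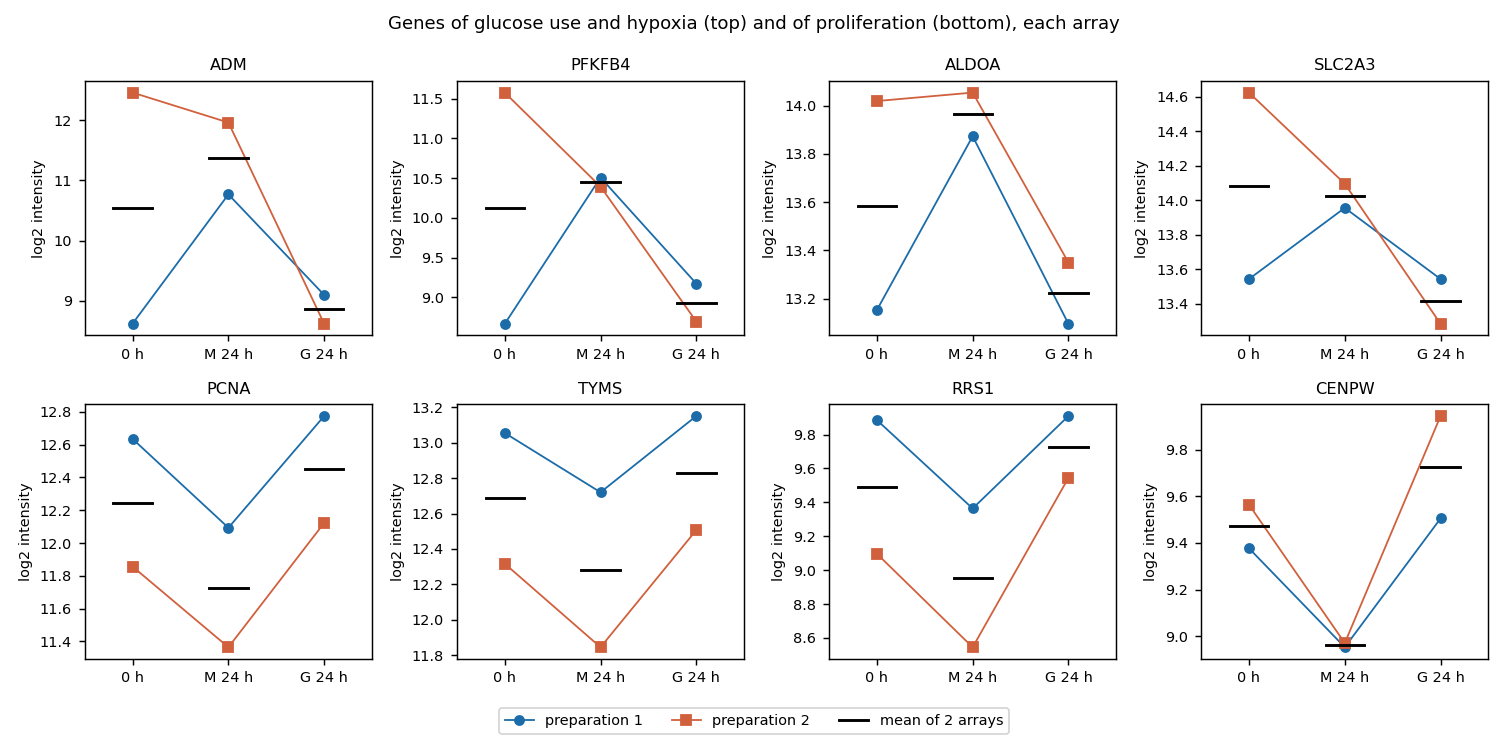
Each panel plots 1 gene: the y axis is the normalized log2 intensity (not starting at 0), the x axis the condition, circles and squares (joined by lines) the arrays of preparations 1 and 2, and black bars the means of 2 arrays. ADM stood at means of 11.4 in arm M and 8.85 in arm G, while the brightest PCNA probe stood at means of 11.7 and 12.4 and its dimmer probe differed by 0.00.

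The second comparison set the mean of the arms at 24 h against 0 h, which is also the comparison that the treatment tags give. Over all features, the changes of the 2 preparations correlated at only 0.06, against 0.35 for G minus M. The log2 level of the chemokine CCL1 fell by 1.82 ± 0.17 to 24 h and that of cystathionine beta-synthase (CBS), which makes cystathionine from homocysteine, fell by 1.03 ± 0.10. The chemokine CCL23 was 1.25 ± 0.13 higher, the IgM Fc receptor FCMR 0.90 ± 0.10, the matrix protein fibulin 5 (FBLN5) 0.84 ± 0.12, the chemokine receptors CCR1 0.75 ± 0.10 and CCR2 0.69 ± 0.10, and the lysosomal protein CD68 0.69 ± 0.10. These 8 genes, with 2 unnamed probes that fell, were the 10 features called by limma with the preparation as a block, and the errors given are of that fit. The adjusted p of the 10 ran from 0.0018 to 0.040. The CD68 call rests on 1 probe, the other kept probes standing at 0.10 and 0.45, whereas the other kept probes of CCL23 (1.12), FBLN5 (0.46) and CCR2 (0.38 to 0.70) were also higher. Without the block limma called 0 of 19454 features, with 266 at an unadjusted p under 0.05. CBS, CCL23, FCMR, CCR1 and CCR2 were picked out after their values were seen. Without 0h replicate 1 the unblocked changes of CD68 and CCR2 turned to -0.01 and -0.38.

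NF-kB target genes fell from 0 h to 24 h as a group. The median over 26 genes was -0.30 (1.23-fold lower) and 15 were lower in both preparations. CD83, a surface marker of activation, fell by 0.63 ± 0.11 and was the single gene past the test when adjusted over the list alone (limma adjusted p = 0.027). NFKBIA was at -0.59 ± 0.30, RELB at -0.44 ± 0.22 and NFKBIB at -0.31 ± 0.12. The ATF4 and amino acid response list fell as a group, with a median of -0.24, 23 of its 26 genes fitted lower and 15 lower in both preparations, including the serine synthesis enzymes PHGDH at -0.74 ± 0.44 and PSPH at -0.55 ± 0.19, and ATF3 at -0.37 ± 0.15. The oxidative phosphorylation list was lower as a group, with a median of -0.10, 40 of its 50 genes fitted lower and 33 lower in both preparations, none of them past the test as a single gene, with CYC1 at -0.37 ± 0.16 and NDUFS7 at -0.24 ± 0.11.

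Camera called each of these 3 lists at adjusted p = 0.00017. The NF-kB and ATF4 lists had adjusted p = 0.98 with an estimated correlation and the oxidative phosphorylation list adjusted p = 0.41 with an estimated correlation. The estimates were 0.44, 0.32 and -0.01 in that order, and -0.01, 0.36 and -0.01 with the block. The loss of the oxidative phosphorylation call therefore did not come from its correlation. In the blocked fit, 14 NF-kB targets and 10 ATF4 genes were lower when adjusted over the list alone. The NF-kB call was lost without 0h replicate 2 (adjusted p = 0.59), without M24h replicate 1 (0.15) and without G24h replicate 1 (0.088), and the ATF4 list turned without 0h replicate 1 (adjusted p = 0.76). Once the preparation was a block, all 3 lists kept their calls without any 1 of the 6 arrays. Over all alternatives the adjusted p ran from 8.3e-13 to 0.98 for NF-kB targets, from 2.6e-16 to 0.98 for the ATF4 list and from 5.3e-05 to 0.54 for oxidative phosphorylation.

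**Figure D3:**
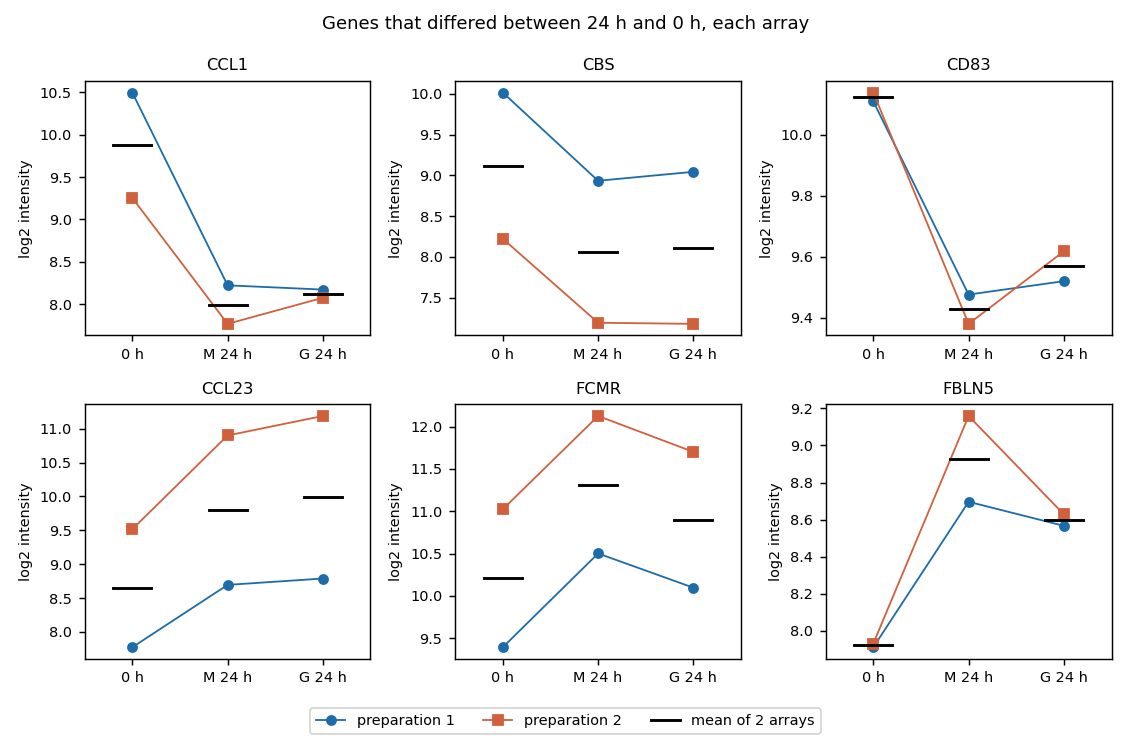
Each panel plots 1 gene: the y axis is the normalized log2 intensity (not starting at 0), the x axis the condition, circles and squares (joined by lines) the arrays of preparations 1 and 2, and black bars the means of 2 arrays. CCL1 stood at a mean of 9.88 at 0 h and at 7.99 and 8.12 in arms M and G, and CCL23 at 8.64, 9.80 and 9.99.

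With the preparation as a block, camera called 8 lists for 24 h against 0 h. In addition to those above, glucose and lactate transporters (median -0.20, adjusted p = 0.019) and ribosome biogenesis (median -0.11, adjusted p = 0.0047) were lower. T cell receptor complex and lineage genes (median 0.08, adjusted p = 0.011), NK and CD8 T cell markers (median 0.21, adjusted p = 0.0043) and the Treg signature (median 0.10, adjusted p = 0.048) were higher. None of the 5 passed in the fit without the block, and in the blocked fit none of the 31 lists passed with an estimated correlation (smallest adjusted p = 0.49 with an estimated correlation).

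CD4 differed by 0.53 ± 0.44, CTLA4 by 0.46 ± 0.62, FOXP3 by 0.11 ± 0.15, IL2RA by 0.25 ± 0.19 and the activation receptor TNFRSF9 by -0.66 ± 0.29. Of the glucose genes, HK2 was at -0.73 ± 0.34 (0.03 and -1.50 in preparations 1 and 2, and -0.22 without 0h replicate 2), SLC2A1 at -0.38 ± 0.30 and SLC2A3 at -0.37 ± 0.30, and HIF1A was at 0.37 ± 0.12. Without 0h replicate 2 SLC2A1 turned to 0.09 and SLC2A3 to 0.18, and without 0h replicate 1 CTLA4 turned to -0.28. The lipid synthesis regulator SREBF1 was at 0.46 ± 0.12. The other named genes of smallest p in the unblocked fit were NUCB2 at 0.62 ± 0.12, MTMR11 at 0.57 ± 0.11, MYBL1 at 0.56 ± 0.13, LINC02348 at 0.52 ± 0.11, PLPP3 at -0.54 ± 0.13, the spliceosomal RNA RNU4-2 at -0.61 ± 0.15 and GPR137 at -0.46 ± 0.11, none past the test. When adjusted over the list alone in the blocked fit, CTLA4, CD4, SREBF1, TM7SF2, GNLY, KLRB1, AIF1 and ITGAX were higher and TNFRSF9, CCR7 and LYZ lower, none of them when adjusted over all genes tested. Of the 28 lists that camera did not call in the unblocked fit, medians ran from -0.20 (glucose and lactate transporters) to 0.21 (NK and CD8 T cell markers). The 9 monocyte markers had a median of -0.14 and a mean of 0.05. Median, mean or camera direction also differed in sign, at medians no further from 0 than -0.04, for fatty acid oxidation, Toll-like receptors, the unfolded protein response, effector cytokines, autophagy and cytosolic ribosomal proteins.

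Each arm was also set against 0 h. In arm M, camera called 6 lists. Glycolytic enzymes (median 0.17, adjusted p = 0.024) and T cell receptor complex and lineage genes (median 0.19, adjusted p = 0.018) rose. The ATF4 response (median -0.33, adjusted p = 0.00019), oxidative phosphorylation (-0.12, 0.00019), ribosome biogenesis (-0.25, 0.00078) and NF-kB targets (-0.22, 0.012) fell. In arm G proliferation genes rose (median 0.18, adjusted p = 0.049). NF-kB targets (-0.30, 0.00025), the hypoxia list (-0.31, 0.00093), glucose and lactate transporters (-0.13, 0.013), the ATF4 response (-0.15, 0.028) and oxidative phosphorylation (-0.07, 0.031) fell. The smallest camera adjusted p in arm M was 0.40 with an estimated correlation and in arm G it was 0.69 with an estimated correlation, so no list passed that way. Fry called oxidative phosphorylation lower in arm G (adjusted p = 0.014), but not with the block (0.069), and in arm M it did so only with the block (0.038, against 0.051). In the blocked fit camera called 9 lists in arm M and 8 in arm G, and none with an estimated correlation (smallest adjusted p = 0.35 in arm M and 0.49 in arm G with an estimated correlation).

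The glycolytic rise in arm M and the hypoxia fall in arm G were not shared by the preparations. The glycolytic medians in arm M were 0.48 and -0.14 in preparations 1 and 2, and the hypoxia medians in arm G were 0.17 and -0.83. Limma called 0 features in either arm, with 388 at an unadjusted p under 0.05 in arm M and 227 in arm G. With the preparation as a block it called 21 in arm M, among them the serine synthesis genes PSAT1, PHGDH and PSPH, which were lower, and 4 in arm G: CCL23 at 1.34 ± 0.15, CCR1 at 0.88 ± 0.12, CCL1 at -1.75 ± 0.20 and CBS at -1.01 ± 0.12, genes chosen after their values were seen. Both contrasts use the same 2 arrays at 0 h, so no overlap between them was taken as evidence.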

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

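The tests of scaling, of culture state, and of monocyte content and arm for the 24 h genes were chosen after the results were seen. The tests against lists matched on brightness were set before their own results were seen, for list shifts whose direction was already known.

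The change from 0 h to 24 h differed between the arms for 5 gene lists by camera on G minus M: glycolytic enzymes (median -0.35), HIF-1 and hypoxia targets (median -0.40), proliferation (0.35), heat shock (0.17) and ribosome biogenesis (0.20), each of them with adjusted p = 0.86 with an estimated correlation.

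For the lower hypoxia and glycolysis genes in arm G, normalization was argued against, since the weakest of the 8 list medians under 4 scalings was -0.31. A trend with probe brightness was argued against too: none of 10000 lists matched on brightness had a median as low as the -0.37 of the 40 genes, a percentile of 0. The matched medians ran from -0.11 to 0.13. Camera had already called both lists against the other genes of these arrays. The percentile therefore bears on brightness only and adds no support for the shift itself. Culture state varying between wells irrespective of the arm stays open: fry in the blocked fit gave adjusted p = 0.66 and 0.69. The shift of -0.36 in the array medians had a standard error of 0.34 in that fit (2 residual degrees of freedom). That error pools all 3 conditions, and the arrays at 0 h stood furthest apart (hypoxia list -0.24 and 0.58). The hypoxia list stood at 0.19 and 0.16 in arm M and at -0.23 and -0.26 in arm G. With 1 array per preparation and condition, the error cannot be read as the spread of the arm difference between wells. A biological difference between the arms stays open as well.

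For the higher proliferation and ribosome biogenesis genes in arm G, normalization was argued against by a weakest list median of 0.20 under the same scalings. A trend with brightness was argued against, the median of 0.30 of the 62 genes lying at percentile 100 of 10000 matched lists. Here too the lists had already been called on the same arrays, so the percentile bears on brightness only. Culture state varying between wells irrespective of the arm stays open by fry in the blocked fit (adjusted p = 0.13 for each list). The shift of 0.33 in the array medians was larger than its standard error of 0.06 in that fit, which also pools all 3 conditions. A biological difference between the arms stays open as well.

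CCL23, CD68, CCR1 and CCR2, which are also abundant in monocytes, were higher at 24 h than at 0 h, CD68 unevenly over its 3 kept probes (0.69, 0.10 and 0.45). A larger share of monocytes as the whole cause was argued against: the 8 monocyte markers other than CD68 had a median change of -0.15 (SD 0.28 over genes), and the 3 at least as bright as CCR1 (LYZ, AIF1 and CST3) of -0.18 (SD 0.40), where the smallest rise of the 4 genes was 0.69. LYZ, at a mean log2 level of 9.03, stood at -0.74 and only -0.08 in preparations 1 and 2, AIF1 and ITGAX were higher over the list alone with the block, and the myeloid gene LST1 was higher in arm M with the block (0.78), so a change within myeloid cells stays open. A rise in 1 arm only was argued against, since their mean G minus M was 0.09 with a standard error of 0.10 over genes, where such a rise needs a size of 1.69. Time in culture, confounded with the handling at 0 h, stays open and untested.

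The change from 0 h ran opposite ways in the 2 preparations for glycolytic enzymes (medians 0.36 and -0.35 in preparations 1 and 2) and for HIF-1 and hypoxia targets (0.28 and -0.67); this difference was not tested. Both arms of a preparation share its 1 array at 0 h, where the lists stood at -0.33 and 0.36 (glycolytic enzymes) and at -0.24 and 0.58 (hypoxia), so that both arms follow is no separate evidence. A lower size of 0.1 in each arm and preparation was set for this after the values were seen, and 9 of 31 lists met the condition at any size.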

How the results depend on the processing

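The alternatives added after the data were seen were normexp offset 16, the brightest 30% of probes, and the block combined with an estimated correlation, fry or left-out arrays. Normexp with offset 50 equalled the setting used, and the filter on detection p and the block for the slide were not run, since the tables used here hold neither. Leaving arrays out aside, 957 of 967 gene results and 97 of 128 list results kept their direction and their side of the threshold; with an array left out this held for 469 of 486 and 80 of 96. In the main fit 0 features passed in any contrast, so that gene results stayed on their side of the threshold says little. What they could show is a turn of sign or a new pass. Leaving arrays out aside, 2 gene results turned and 8 passed, and with an array left out 17 turned. The cause of the changes below was not tested. By design, a left-out array leaves a condition with 1 array, assumed to vary like the others. Without the block that condition then holds 1 preparation, so part of the difference between preparations enters the contrast. For proliferation genes that difference had a median of -0.81. With the block none of the called lists reversed its direction when an array was left out. Adjusted over all features, none passed for G minus M under the 18 alternatives run for single features. The preparation block brought 10 features past the threshold for 24 h against 0 h, 21 for arm M and 4 for arm G against 0 h, and 8 lists for 24 h against 0 h in place of 3. Median scaling gave 8 lists for G minus M in place of 5, and the brightest 30% of probes 5 for 24 h against 0 h. Without a filter heat shock had adjusted p = 0.087. MYD88 (G minus M) turned to 0.003 under cyclic loess and 0.123 under median scaling. With an estimated correlation 0 lists passed in either contrast: the 5 lists of G minus M had adjusted p = 0.86, oxidative phosphorylation 0.41, NF-kB targets and the ATF4 list 0.98. Fry called 0 lists for G minus M (adjusted p = 1 for the 5 lists) and 1 for 24 h against 0 h, oxidative phosphorylation, with 0.98 for NF-kB targets and the ATF4 list. The block with an estimated correlation called 0 lists in either contrast (0.57 for the 5 lists, 0.54 for oxidative phosphorylation and the ATF4 list, 0.49 for NF-kB targets). The block with fry called 1 list in each, oxidative phosphorylation, higher for G minus M (adjusted p = 0.043) and lower for 24 h against 0 h (0.049), with 0.69 for glycolytic enzymes, 0.66 for the hypoxia list, 0.13 for proliferation, heat shock and ribosome biogenesis, 0.28 for NF-kB targets and 0.37 for the ATF4 list.

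Over left-out arrays, with and without the block, lists called ranged from 2 to 12 for G minus M and from 4 to 10 for 24 h against 0 h. Adjusted p ranged from 8.9e-15 to 0.56 for glycolytic enzymes, 4.3e-23 to 0.084 for the hypoxia list, 4.3e-23 to 0.98 for proliferation, 0.0064 to 0.5 for heat shock, 6e-08 to 0.66 for ribosome biogenesis, 8.3e-13 to 0.59 for NF-kB targets and 2.6e-16 to 0.76 for the ATF4 list. For G minus M the log2 difference ranged from -0.38 to 0.063 for LDHA, -0.282 to 0.064 for FOXP3, -0.374 to 0.152 for IL2RA, -0.669 to 0.816 for CTLA4, -0.235 to 0.042 for IKZF2, -0.269 to 0.263 for MYD88 and -0.479 to 0.526 for MYC. For 24 h against 0 h it ranged from -0.007 to 1.387 for CD68, -0.376 to 1.753 for CCR2, -0.275 to 1.198 for CTLA4, -0.859 to 0.09 for SLC2A1 and -0.906 to 0.176 for SLC2A3. Signal over background limits dim genes: the 3 TLR8 probes lay under the brightness limit of 6.81.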

Other observations

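The test of the liver X receptor targets and the count over splits were set before their results were seen; the look at differences between preparations was chosen after the results were seen.

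The 2 Treg preparations differed from each other in more features than the conditions did in any of the 4 contrasts. That count rests on 3 arrays a side, against 2 per condition. Typical sizes lay closer, with a median absolute log2 difference of 0.15 between preparations and of 0.087 to 0.114 in the contrasts. With 1 preparation on each side, the p-values measure the spread between arrays within preparations, not that between preparations. With the condition in the limma fit, 4658 of 19437 features differed between preparations (2288 higher in preparation 2, 2370 lower; genes of the sex chromosomes' Y part and XIST were left out). Of 38 proliferation genes, 37 were lower in preparation 2 past the test (median -0.81), as were 14 of 24 ribosome biogenesis genes (median -0.33) and 17 of 26 ATF4 response genes (median -0.41), in which amino acid synthesis and transfer RNA charging genes are held. NF-kB targets were higher in preparation 2 (16 of 26 past the test, median 0.46), as were effector cytokines and cytotoxic molecules (11 of 18, median 0.56), T cell receptor complex and lineage genes (12 of 21, median 0.38) and Treg signature genes (14 of 30, median 0.30). Members past the test in the other direction were 4 Treg signature, 3 effector, 2 ATF4, 1 NF-kB and 1 T cell lineage gene. Some markers of other cell types moved with these groups. NK and CD8 T cell markers were higher in preparation 2 (4 of 7 past the test, median 0.54), as were monocyte markers (5 of 9, median 0.69, with 1 lower past the test). Camera did not call the markers of B cells (median 0.06, adjusted p = 0.089), dendritic cells (-0.04, 0.39) or platelets and erythroid cells (0.00, 0.26). Camera called 15 of the 31 lists between preparations and 0 with an estimated correlation.

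Without the condition in the fit the preparations differed in 3704 features, and the highest of the other 9 splits of the 6 arrays into 3 and 3 gave 0. As 1 of 10 splits gave as many features, the real one, the splits are too few for a share under 0.05.

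SREBF1 (0.46 ± 0.12), MYLIP (0.49 ± 0.15), ABCG1 (0.62 ± 0.22) and ABCA1 (0.78 ± 0.79), targets of the liver X receptors that sense cholesterol derivatives, stood higher at 24 h than at 0 h in both preparations. With the preparation as a block the standard errors were 0.1, 0.12, 0.12 and 0.16 in that order. The hypothesis that targets of these receptors rise together was tested on 6 further measured targets whose values had not been looked at (SCD, LPCAT3, NR1H3, SMPDL3A, APOC1 and PLTP). Their median change was -0.08 with a standard error of 0.05 over genes, at percentile 7.6 of 10000 lists matched on brightness. That argues against a rise shared by these 6 targets. It does not decide whether the receptors drove the rise of SREBF1, MYLIP, ABCG1 and ABCA1, which were left out of the test.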
